A study of Mus musculus with 4 samples.

How the data were processed

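T cell receptor (TCR) chains were sequenced from thymic CD4 single-positive cells of 7-week-old C57BL/6 mice. The 4 samples formed 4 groups of 1 sample each. CTRL mice carried a Foxp3-GFP reporter and floxed Cic alleles. KO mice carried in addition Vav1-Cre, which deletes floxed genes in blood cells, so that their T cells lack the transcriptional repressor Capicua (CIC). Regulatory T (Treg) cells were sorted as CD4+CD8-CD25+GFP+ and non-Treg cells as CD4+CD8-GFP-. The alpha and the beta chain of each sample were sequenced separately, which gave 8 files.

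Per the labels' protocols, total RNA was reverse transcribed and amplified with V and C segment primers. Shared primer sites then served for a further round of amplification, and a 6-nucleotide internal barcode sat next to the C primer. No molecular identifier is described. The aligner, the caller, the treatment of PCR errors and the genome build are not given in the sources used here. The deposited files list, per row, a CDR3 amino acid sequence, a V segment, a J segment and a whole number of copies. These copies are counts as the authors deposited them, with no normalization. Tested on the files, the lowest value was 2 copies in each of the 8 files, the conserved Cys and Phe at the ends of the CDR3 were left out, and no nucleotide sequence was given.

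A clonotype was defined as a unique combination of V segment, J segment and CDR3 amino acids. A filter for productive CDR3s removed 0 rows. Without molecular identifiers, copies are not independent molecules, so shares were taken over unique clonotypes and shares of copies served as an alternative. Each share has an exact binomial (Clopper-Pearson) 95% interval, and each ratio of shares a log-normal (Katz) 95% interval. A segment was called higher or lower where that interval excluded 1 and the segment held at least 1% of the clonotypes of either library. These intervals cover counting error only. Variants of one receptor made by PCR errors are listed as separate clonotypes, so the intervals are too narrow wherever such variants are frequent. With 1 sample per group there was no replicate check, and no p-value was computed. The calls compare libraries, not genotypes or cell types.

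Segments to be named were fixed before the data were examined. For KO against CTRL, these were the 5 called V segments with the largest ratio in each direction and the 2 such J segments, per chain and cell type. For Treg against non-Treg the numbers were 3 and 1. The 3 clonotypes with most copies per library were also to be named. The fixed alpha lists were J-alpha segments near the V segments (TRAJ40 and higher numbers) and far from them (TRAJ22 and lower), and the V-alpha segments TRAV15 to TRAV21. The last list was chosen to represent the J end of the locus, but it takes all copies of these segments, whose positions were not checked. The fixed beta lists were the TRBJ1 cluster, the superantigen-sensitive group TRBV12-1, TRBV12-2, TRBV15 and TRBV16, and the TRBV13 family. CDR3s of at most 12 residues were called short and those of at least 16 long, with the 2 anchor residues added. Further features were a Cys within 2 positions of the CDR3 centre and, for the beta chain, hydrophobic residues at both positions 6 and 7 counted from the conserved Cys. Marker combinations were TRAV11 with TRAJ18 for invariant NKT cells, TRAV1 with TRAJ33 for MAIT cells, and any gamma or delta segment for gamma-delta T cells.

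Richness and diversity were computed on all copies and after thinning each library of a chain to the copies of the smallest one, 242368 for alpha and 309035 for beta, in 100 seeded draws. Sharing was also computed with the larger non-Treg list of a chain thinned to the number of clonotypes of the smaller one. Of 144 segment names in the files, 143 matched symbols of the RefSeq annotation of GRCm38.p6, and TRAV9-3 did not. No coordinates were used. Many mouse TRAV segments exist in near-identical copies, marked D in their names, which short reads can fail to separate. TRAV names that differ only in such a mark are therefore uncertain. The script for segment calls was tested on simulated data. The same 4 of the more frequent segments were changed 2-fold, up or down, in each of 50 draws of independent clonotypes. The script called 85% of them for the alpha chain and 89.5% for the beta chain at the depth of the Treg comparison of KO against CTRL. At the depth of the same comparison in non-Treg cells it called 100% for both chains. Real lists hold error variants, which are not independent, so these rates do not carry over to them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

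The alternatives planned were counting copies, a minimum of 5 copies, merging a clonotype into another of the same V, J and length that differs at 1 residue and has at least 20 times its copies, other thinning depths, other windows for the CDR3 features, another division of the TRAJ lists, and sharing by CDR3 alone. Added after seeing the data were Treg clonotypes of at least 100 copies only, leaving out Treg clonotypes under 20 copies that the non-Treg library of the same genotype also lists, that step together with merging, and collapsing TRAV copies. The 100-copy minimum and the low-copy step changed the Treg libraries only. Treg over non-Treg ratios under them therefore set filtered Treg lists against non-Treg lists without that filter. The deletion of Cic itself cannot be read from TCR sequences and was not checked.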

Results

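The TCR repertoire of thymic Treg and non-Treg cells was profiled in CTRL and CIC-deficient KO mice, with 1 sample per group and separate alpha and beta chain libraries. The design asks how loss of CIC in blood cells alters the receptors of each subset, and how Treg receptors differ from those of non-Treg cells of the same genotype. The labels do not say whether the Treg and non-Treg cells of a genotype came from the same mouse. For the alpha chain, the non-Treg libraries held 2893266 copies of 110819 clonotypes in CTRL and 2825718 copies of 79955 clonotypes in KO. The Treg libraries held 242368 copies of 730 clonotypes and 296719 copies of 964 clonotypes. For the beta chain, the non-Treg libraries held 3179358 copies of 78520 clonotypes in CTRL and 3439960 copies of 52806 in KO. The beta Treg libraries held 309035 copies of 565 clonotypes in CTRL and 376545 copies of 3038 clonotypes in KO. Most Treg copies lay in few clonotypes: those of at least 100 copies numbered 175 in CTRL and 252 in KO for alpha, and 85 and 126 for beta, and held between 96.8% and 98.5% of each library. All percentages below are of unique clonotypes unless copies are named, all intervals are 95% intervals of counting error, and no value has replicates.

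In non-Treg cells, the KO beta chains used the TRBJ1 cluster more, and the TRBJ2 cluster less, than the CTRL beta chains. TRBJ1 segments were carried by 48.4% of KO clonotypes (47.9 to 48.8) and by 37.1% of CTRL clonotypes (36.8 to 37.5), a ratio of 1.30 (1.29 to 1.32). All 12 TRBJ segments were called: the 6 of the TRBJ1 cluster were higher and the 6 of the TRBJ2 cluster lower in KO. TRBJ1-2 was at 7.03% in KO and 4.54% in CTRL, a ratio of 1.55 (1.48 to 1.62), and TRBJ1-3 had a ratio of 1.43 (1.37 to 1.49). TRBJ2-2 was at 2.18% and 3.17%, a ratio of 0.686 (0.641 to 0.736). TRBJ2-5, the most used J segment of the CTRL library, was at 14.7% and 18.9%, a ratio of 0.776 (0.757 to 0.796).

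Among TRBV segments with at least 1% of clonotypes, 15 of 19 were called in non-Treg cells, 6 higher and 9 lower in KO. TRBV31, which lies downstream of the constant regions in inverted orientation and rearranges by inversion, had the largest ratio above 1. It was carried by 13.6% of KO clonotypes (13.3 to 13.9) and 9.68% of CTRL clonotypes (9.47 to 9.89), a ratio of 1.41 (1.36 to 1.45). The next were TRBV13-3 with 1.20, TRBV29 with 1.17, TRBV13-1 with 1.14 and TRBV26 with 1.13, the last of which fell to 0.970 by copies. TRBV12-1 had the lowest ratio, 0.673 (0.617 to 0.734), followed by TRBV2 with 0.721 (0.696 to 0.748), TRBV14 with 0.781 and TRBV15 with 0.799. TRBV4 had a ratio of 0.831, which turned to 1.06 (1.01 to 1.12) among clonotypes of at least 5 copies. The TRBV13 family, which encodes the Vbeta8 chains, made up 19.1% of KO and 16.7% of CTRL clonotypes, a ratio of 1.15 (1.12 to 1.17). The group of TRBV12-1, TRBV12-2, TRBV15 and TRBV16, whose chains are removed by endogenous superantigens in I-E-positive mice, made up 10.1% and 11.9%, a ratio of 0.850 (0.824 to 0.878). C57BL/6 mice express no I-E.

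**Figure D1:**
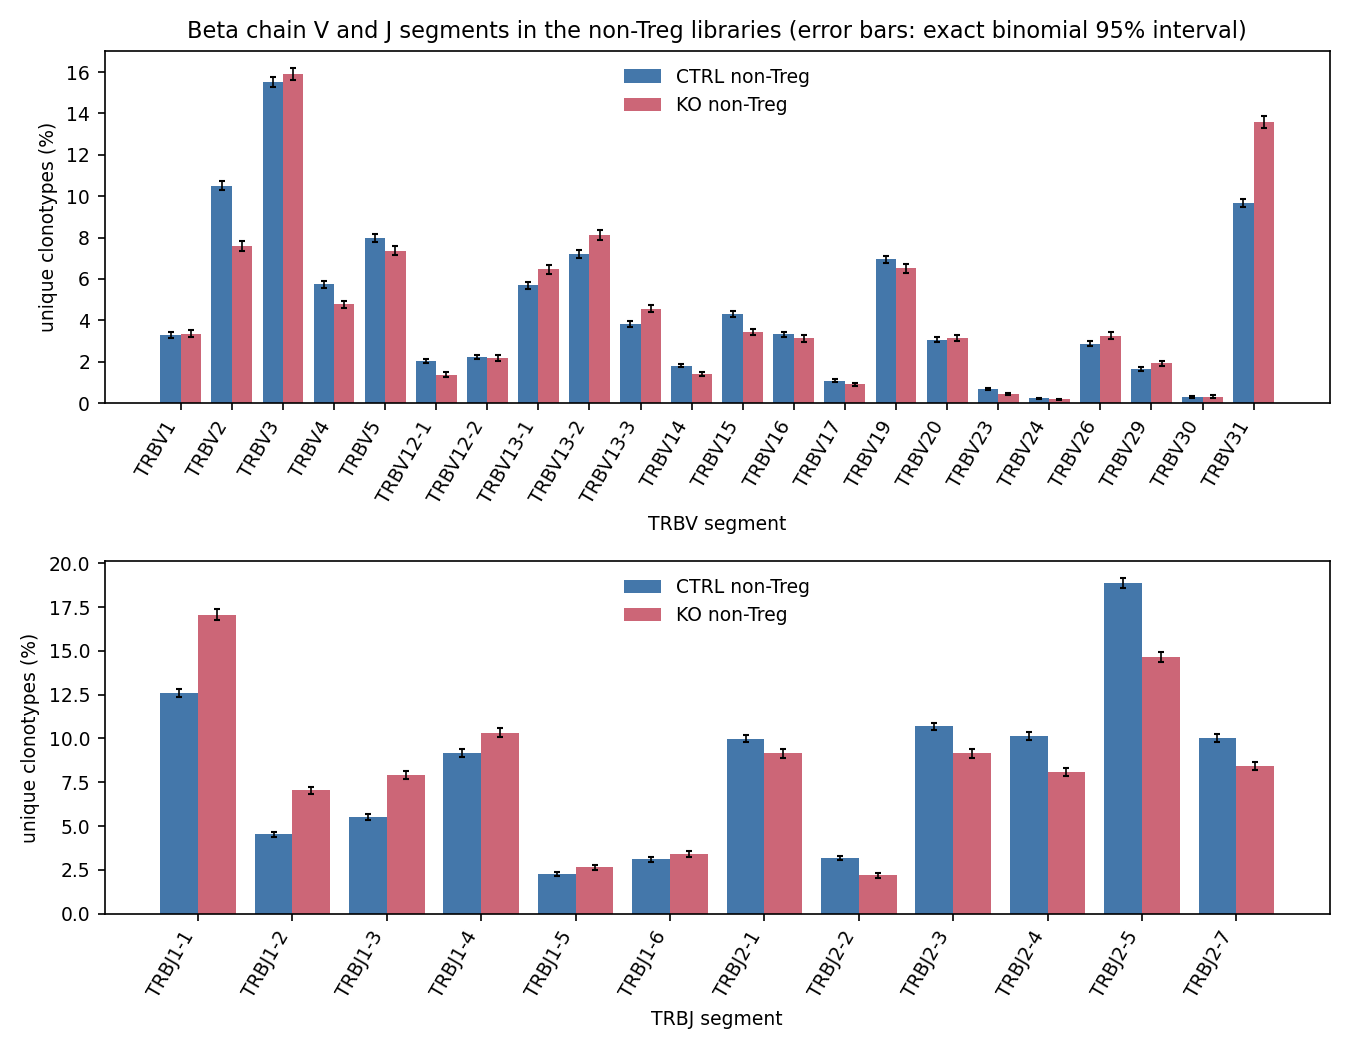
Share of unique beta chain clonotypes (%, y axis) that carry each TRBV segment (top) and each TRBJ segment (bottom) in the CTRL and KO non-Treg libraries, 1 library each, with exact binomial 95% intervals as error bars. TRBV31 stood at 13.6% in KO and 9.68% in CTRL, and the 6 TRBJ1 segments were higher and the 6 TRBJ2 segments lower in KO.

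The alpha chains of non-Treg cells differed less. Of 37 TRAV segments with at least 1% of clonotypes, 13 were higher and 13 lower in KO. The largest ratios were those of TRAV17 with 1.28 (1.16 to 1.40), TRAV5-1 with 1.27, TRAV7D-2 with 1.23, TRAV10 with 1.18 and TRAV9D-1 with 1.18. The lowest were those of TRAV13D-2 with 0.778 (0.720 to 0.841), TRAV8D-1 with 0.804, TRAV7-5 with 0.812, TRAV7-6 with 0.841 and TRAV7D-6 with 0.861. J-alpha segments near the V segments, which are used by early rearrangements, were carried by 24.0% of KO and 26.6% of CTRL clonotypes, a ratio of 0.903 (0.889 to 0.918). Those far from the V segments were carried by 33.6% and 31.5%, a ratio of 1.07 (1.054 to 1.082). TRAJ50 and TRAJ56, both near the V segments, had the lowest J ratios, 0.703 and 0.767, and TRAJ2 and TRAJ15, both far, the highest, 1.21 and 1.14. TRAV15 to TRAV21 were not called as a list, with 4.47% in KO and 4.35% in CTRL (ratio 1.03, 0.984 to 1.07), although TRAV17 within it was called higher.

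The KO non-Treg libraries held fewer clonotypes at similar depth, 0.721 times the CTRL number for alpha and 0.673 times for beta, but more clonotypes of at least 100 copies, 1.37 and 1.22 times. At equal copies, thinning left 52101.6 ± 93.0 clonotypes in KO and 67037.7 ± 113 in CTRL for alpha, and 38354.0 ± 73.0 and 55885.8 ± 87.1 for beta (mean ± SD over draws). Long CDR3s were less frequent in KO, at 5.18% against 5.83% for alpha (ratio 0.888, 0.855 to 0.922) and 8.43% against 9.72% for beta (ratio 0.866, 0.836 to 0.897). Short CDR3s had a ratio of 1.01 in both chains, with intervals that include 1. Mean lengths were 13.4 residues for alpha and 13.8 for beta in both genotypes. A Cys near the CDR3 apex, a feature that thymic selection removes, was found in 0.258% of KO and 0.171% of CTRL beta clonotypes, a ratio of 1.51 (1.19 to 1.92). This ratio was 0.840 (0.559 to 1.26) once error variants were merged, and 1.07 (0.901 to 1.28) for the alpha chain. Hydrophobic residues at positions 6 and 7, a mark of self-reactive beta chains, were found in 528 KO clonotypes and 893 CTRL clonotypes, a ratio of shares of 0.879 (0.790 to 0.979), or 0.913 (0.823 to 1.01) when counted from the residue after the conserved Cys.

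The non-Treg libraries of the genotypes shared many alpha clonotypes and few beta clonotypes. Of the CTRL alpha clonotypes, 25.5% were also listed in KO, and of the KO ones 35.4% in CTRL. For beta the shares were 8.32% and 12.4%. The alpha clonotypes with most copies were largely common to both: TRAV14-3 with TRAJ22 and CDR3 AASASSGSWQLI had 2296 copies in CTRL and 1869 in KO. TRAV14D-3/DV8 with TRAJ42 and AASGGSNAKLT had 1848 and 1653 copies, TRAV8D-1 with TRAJ30 and ATDTNAYKVI 1837 and 1627, TRAV13D-1 with TRAJ31 and ALERNSNNRIF 993 and 1943, and TRAV4D-4 with TRAJ30 and AADTNAYKVI 1433 and 1804. The leading beta clonotypes of both libraries carried TRBV31, such as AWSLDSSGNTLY with TRBJ1-3 at 2114 copies in CTRL and 405 in KO, and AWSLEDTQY with TRBJ2-5 at 1285 and 2902. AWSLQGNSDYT with TRBJ1-2 had 1851 and 303 copies, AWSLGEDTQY with TRBJ2-5 had 208 and 2486, and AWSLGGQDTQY with TRBJ2-5 had 965 and 2122. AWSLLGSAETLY with TRBJ2-3 had 1966 copies in CTRL and was not listed in KO. The invariant NKT combination of TRAV11 and TRAJ18 gave 15 clonotypes with 1725 copies in CTRL and 14 with 1288 copies in KO, and its canonical CDR3 VVGDRGSALGRLH held 1603 and 1180 of these copies. The MAIT combination gave 2 clonotypes with 36 copies and 3 with 19 copies. Neither combination was listed in the Treg libraries. No segment with a gamma (TRG) or delta (TRD) name was listed in any library. Only alpha and beta chains were sequenced, so this absence cannot show whether gamma-delta T cells were present. TRAV segments that delta chains can also use, with DV in their names, were listed.

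At equal copies, KO Treg cells held 1.31 times the alpha and 5.28 times the beta clonotypes of CTRL Treg cells, and among clonotypes of at least 100 copies 1.44 and 1.48 times. Of the alpha chain, KO against CTRL, Treg cells gave 8 TRAV segments higher and 7 lower of 41 with at least 1% of clonotypes. TRAV14D-3/DV8 was carried by 7.16% of KO and 2.05% of CTRL clonotypes, a ratio of 3.48 (2.01 to 6.04). The others named above 1 were TRAV14D-1 with 3.22, TRAV6D-3 with 3.10, TRAV13D-2 with 3.03 and TRAV9D-4 with 2.83. With TRAV copies collapsed, TRAV13D-2 turned to 0.533 (0.332 to 0.856). TRAV8D-2 was carried by 0.415% of KO and 6.85% of CTRL clonotypes, a ratio of 0.0606 (0.0220 to 0.167). TRAV17 had a ratio of 0.0841 (0.0107 to 0.663), from 1 KO and 9 CTRL clonotypes. TRAV4D-3 was at 1.14% and 8.63%, a ratio of 0.132 (0.0702 to 0.249). TRAV5D-4 had a ratio of 0.220 and TRAV7D-6 one of 0.252. Among J segments the ratios were 12.9 for TRAJ48, from 17 and 1 clonotypes, and 5.81 for TRAJ45, from 23 and 3. They were 0.273 for TRAJ37 and 0.347 for TRAJ39. J-alpha segments near the V segments were at 27.9% in KO and 19.5% in CTRL, a ratio of 1.43 (1.20 to 1.72), and far ones at 24.9% and 33.0%, a ratio of 0.754 (0.649 to 0.877). TRAV15 to TRAV21 were at 2.70% and 3.29% (ratio 0.820, 0.475 to 1.42). Long CDR3s were at 4.25% and 1.64%, a ratio of 2.59 (1.37 to 4.89), but at 3.31% and 3.23% of copies, and short ones at 24.2% and 28.8%, a ratio of 0.840 (0.716 to 0.986). Among clonotypes of at least 100 copies, called TRAV segments numbered 2, namely TRAV4D-3 with a ratio of 0.208 (0.0582 to 0.746) and TRAV5D-4 with 0.253 (0.0817 to 0.780), and the near J-alpha ratio was 1.46 (0.988 to 2.15). With error variants merged that ratio was 1.16 (0.871 to 1.55), and with the J lists divided elsewhere 1.27 (0.983 to 1.64).

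For the beta chain of Treg cells, 3 TRBV segments were higher and 10 lower in KO of 18 with at least 1% of clonotypes. The size or direction of several of these ratios depended on low-copy clonotypes of the KO library. TRBV31 was carried by 37.2% of KO (35.5 to 38.9) and 9.56% of CTRL clonotypes (7.26 to 12.3), a ratio of 3.89 (3.01 to 5.04). By copies it was lower in KO, at 14.2% against 20.98%, and among clonotypes of at least 100 copies its ratio was 0.385 (0.116 to 1.28). TRBV13-1 had a ratio of 1.61 and was at 23.1% of KO and 8.18% of CTRL copies. TRBV13-2 had a ratio of 1.69, and 0.999 by copies. The lowest ratios were those of TRBV4 with 0.186, TRBV26 with 0.217, TRBV12-1 with 0.243, TRBV20 with 0.259 and TRBV1 with 0.292. With low-copy shared clonotypes left out these were 0.506, 0.690 (0.295 to 1.61), 0.510, 0.542 and 0.253 (0.0513 to 1.25), in the same order. The named J segments were TRBJ1-2 with 6.73, TRBJ2-2 with 6.60, from 71 KO and 2 CTRL clonotypes, TRBJ2-4 with 0.477 and TRBJ2-1 with 0.697. With low-copy shared clonotypes left out and error variants merged, TRBJ1-2 turned to 0.856 (0.236 to 3.11) and TRBJ2-4 to 1.03 (0.599 to 1.76), and TRBJ2-1 was at 1.01 (0.432 to 2.37) among clonotypes of at least 100 copies. The TRBJ1 cluster was at 46.7% and 34.0%, a ratio of 1.37 (1.22 to 1.55), and at 1.12 (0.761 to 1.66) among clonotypes of at least 100 copies. The superantigen-sensitive group had a ratio of 0.516 (0.415 to 0.642), but was at 15.2% and 17.4% of copies. TRBV12-1 gave 81 of its 261 KO and 62 of its 94 CTRL clonotypes, so the group ratio mainly follows that segment. The TRBV13 family had a ratio of 1.16 (0.988 to 1.36). The hydrophobic doublet, at 1.32% and 0.354%, was not called (ratio 3.72, 0.902 to 15.3), and a Cys near the apex was at 0.395% and 2.65%, a ratio of 0.149 (0.0700 to 0.316). With low-copy shared clonotypes left out, the doublet was called, with 6.45 (1.498 to 27.8), and the Cys was not, with 0.597 (0.273 to 1.30). Both doublet ratios rest on at most 2 CTRL clonotypes, with 4 copies in total. No TRBV segment was called among clonotypes of at least 100 copies, 85 in CTRL and 126 in KO. So few clonotypes also widen the intervals. Of 25 segments named for this comparison in both chains, 23 kept their direction at that minimum and 2 stayed called. These clonotypes are part of the lists in which the segments were picked, so agreement in direction is partly built in.

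**Figure D2:**
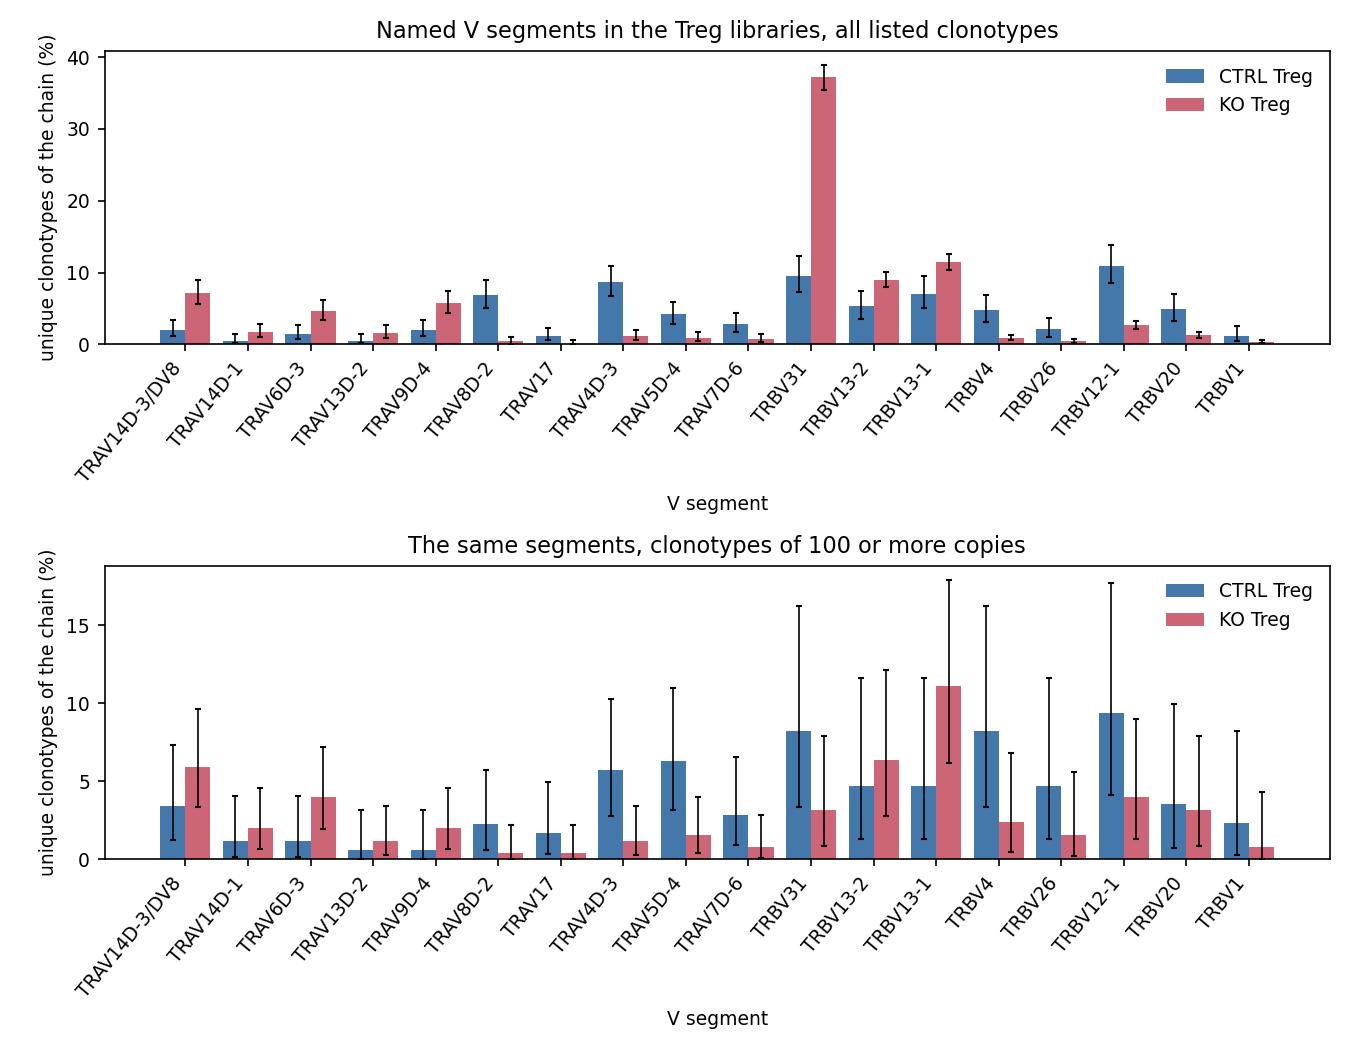
Share of unique Treg clonotypes of the chain (%, y axis) that carry each V segment named for KO against CTRL (x axis), among all listed clonotypes (top) and among those of at least 100 copies (bottom), 1 library per genotype, with exact binomial 95% intervals as error bars. TRBV31 stood at 37.2% in KO among all clonotypes and at 3.17% among those of at least 100 copies, while TRAV4D-3 was lower in KO in both panels.

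The low-copy KO beta clonotypes were mostly shared with one other library. Of 1625 KO Treg beta clonotypes at 2 copies, 90.7% (89.2 to 92.1) were also listed in the KO non-Treg library and 12.3% (10.7 to 14.0) in the CTRL non-Treg library. Of the 136 CTRL Treg beta clonotypes at 2 copies, 4.41% (1.64 to 9.36) were listed in the CTRL non-Treg library. At any copy number, 76.9% of KO Treg beta clonotypes were listed in KO non-Treg, against 11.9% (6.82 to 18.9) of those with at least 100 copies. With clonotypes under 20 copies that the non-Treg library of the same genotype lists left out, the KO beta library kept 719 clonotypes, and with error variants merged as well it kept 146, against 100 in CTRL. The corresponding alpha numbers after both steps were 369 in KO and 247 in CTRL. The leading Treg clonotypes held large shares of copies. The first in CTRL were TRBV31 with TRBJ2-4 and CDR3 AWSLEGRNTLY, at 10.8% of copies, and TRAV8D-2 with TRAJ9 and ATDANMGYKLT, at 6.59%. In KO they were TRBV31 with TRBJ2-5 and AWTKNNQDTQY, at 7.66%, and TRAV9D-4 with TRAJ40 and AVSMLAGNYKYV, with 7423 copies. The CTRL beta clonotype was also listed in KO non-Treg with 5 copies and the KO beta clonotype in CTRL Treg with 2 copies, while these alpha clonotypes were listed in no other library. The next alpha clonotypes were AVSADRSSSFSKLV (TRAV9D-4, TRAJ50) at 3.13% and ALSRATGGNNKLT (TRAV9D-3, TRAJ56) at 2.97% in CTRL, and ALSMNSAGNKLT (TRAV9D-3, TRAJ17) at 2.26% and ATQGTGSKLS (TRAV8D-1, TRAJ58) at 2.21% in KO. The next beta clonotypes were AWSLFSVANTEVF (TRBV31, TRBJ1-1) at 6.68% and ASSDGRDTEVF (TRBV13-1, TRBJ1-1) at 4.86% in CTRL, and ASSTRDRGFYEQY (TRBV13-1, TRBJ2-7) at 5.31% and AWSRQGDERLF (TRBV31, TRBJ1-4) at 4.09% in KO. The Treg libraries of the genotypes shared 3 alpha and 4 beta clonotypes. In CTRL Treg, 2 of these beta clonotypes had 2 copies and 2 had 3 to 4. In KO Treg, 3 of them had at least 1000 copies. Of 49 CTRL Treg beta clonotypes of at least 1000 copies, 12 were listed in KO non-Treg, at a median of 5 copies. In CTRL non-Treg 7 were, at a median of 16. Whether such low-copy listings are clonotypes common to both samples or reads that crossed was not tested.

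**Figure D3:**
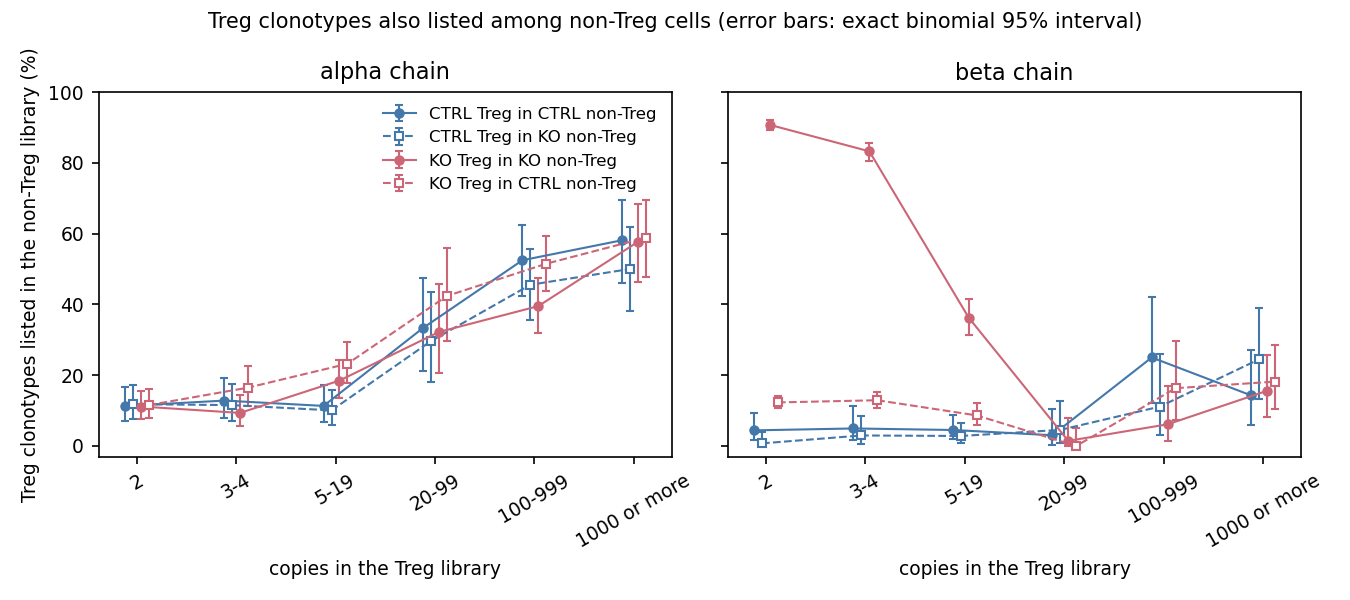
Share of Treg clonotypes (%, y axis) also listed in a non-Treg library, by copies in the Treg library (x axis), for the alpha chain (left) and the beta chain (right), with exact binomial 95% intervals as error bars; solid lines compare libraries of the same genotype and dashed lines libraries of different genotypes. KO Treg beta clonotypes at 2 copies stood at 90.7% in KO non-Treg, far above the other 3 beta comparisons at that copy number.

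In CTRL mice, Treg against non-Treg cells, TRBV12-1 was carried by 10.97% of Treg clonotypes (8.52 to 13.8) and 2.05% of non-Treg clonotypes (1.96 to 2.16), a ratio of 5.34 (4.20 to 6.79). This was the only TRBV segment still called with Treg clonotypes of at least 100 copies set against all non-Treg clonotypes, with 4.58 (2.36 to 8.88). TRBV29 had a ratio of 3.97 and TRBV13-3 one of 2.83, while TRBV2 had one of 0.269, TRBV1 of 0.376 and TRBV16 of 0.478. Of 19 TRBV segments, 4 were higher and 4 lower. TRBJ2-4 was at 17.9% in Treg and 10.1% in non-Treg cells, a ratio of 1.76 (1.48 to 2.11), and TRBJ2-2 had a ratio of 0.112, from 2 Treg clonotypes. The superantigen-sensitive group was higher in Treg cells, with 1.40 (1.16 to 1.68), but 62 of its 94 Treg clonotypes carried TRBV12-1. TRBV16 of the same group was lower, so the group ratio does not describe each member. The TRBV13 family was higher too, with 1.39 (1.19 to 1.61), but stood at 0.986 with Treg clonotypes of at least 100 copies. The TRBJ1 cluster had a ratio of 0.915 (0.815 to 1.03).

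Of 40 TRAV segments in the same comparison, 11 were higher and 10 lower in CTRL Treg cells. TRAV8D-2 had a ratio of 6.57, TRAV4D-3 one of 4.08 (3.21 to 5.19) and TRAV6-1 one of 2.57, against 0.141 for TRAV8D-1, 0.312 for TRAV14D-1 and 0.348 for TRAV13D-2, the last of which was 1.17 (0.862 to 1.58) with TRAV copies collapsed. TRAJ16 had a ratio of 2.39, and TRAJ48, with 1 Treg clonotype, one of 0.0657. J-alpha segments near the V segments were lower in Treg cells, with 0.731 (0.630 to 0.847), and far ones were not called, with 1.049 (0.945 to 1.16). TRAV15 to TRAV21 had a ratio of 0.755 (0.509 to 1.12). Short alpha CDR3s were more frequent in Treg cells, with 1.25 (1.12 to 1.41), and long ones less, with 0.282 (0.161 to 0.494), while by copies long ones were at 3.23% in Treg and 3.24% in non-Treg cells. A Cys near the apex was listed in 15 of 565 CTRL Treg beta clonotypes, 2.65% (1.49 to 4.34), against 0.171% in non-Treg cells. By copies it was at 1.42% and 0.0579%. With error variants merged this Treg library held 101 clonotypes, so such variants can affect its Cys share. For alpha a Cys near the apex was at 0.822% and 0.256%, a ratio of 3.21 (1.43 to 7.18), but at 0.0111% and 0.164% of copies. With at least 100 copies required of Treg clonotypes only, TRAV segments called numbered 4. TRAV8D-2 was no longer one of them, with 2.19 (0.830 to 5.78).

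In KO mice, TRBV12-1 was again higher in Treg cells, at 2.67% against 1.38%, a ratio of 1.93 (1.54 to 2.42). The ratio was 2.87 (1.21 to 6.80) with a minimum of 100 copies in Treg cells and all non-Treg clonotypes kept. TRBV13-1 had a ratio of 1.77 (1.59 to 1.96), and 1.72 (1.047 to 2.82) at that minimum. TRBV31 had a ratio of 2.74 (2.60 to 2.88) over all clonotypes and one of 0.233 (0.0890 to 0.612) at that minimum, and was at 14.2% of Treg and 34.0% of non-Treg copies. TRBV1 had a ratio of 0.108, TRBV26 of 0.141 and TRBV4 of 0.186. Of 18 TRBV segments, 7 were higher and 10 lower over all clonotypes. With low-copy shared clonotypes left out and error variants merged, 1 was called, TRBV12-1, and TRBV26 was at 1.049 (0.478 to 2.30), TRBV4 at 0.484 (0.184 to 1.27) and TRBV1 at 0.174 (0.0247 to 1.23). TRBJ2-3 had a ratio of 1.23, which became 0.694 (0.355 to 1.36) at the higher minimum, and TRBJ1-1 one of 0.893. The TRBV13 family was higher in Treg cells, with 1.41 (1.32 to 1.495). A Cys near the apex was at 0.395% in Treg and 0.258% in non-Treg cells (ratio 1.53, 0.851 to 2.76). The superantigen-sensitive group was lower, with 0.848 (0.753 to 0.955), but higher by copies, at 15.2% against 7.41%.

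For the KO alpha chain, 8 of 38 TRAV segments were higher and 7 lower in Treg cells. TRAV6D-3 had a ratio of 2.66 (1.99 to 3.56), TRAV4D-4 one of 2.26 (1.84 to 2.77) and TRAV9D-3 one of 2.19. The lowest were 0.103 for TRAV17, from 1 Treg clonotype, 0.306 for TRAV5D-4 and 0.336 for TRAV6D-6. TRAV6D-3 and TRAV4D-4 were also called with Treg clonotypes of at least 100 copies set against all non-Treg clonotypes, with 2.26 (1.23 to 4.17) and 1.99 (1.30 to 3.03). With low-copy shared clonotypes left out and error variants merged, TRAV4D-4 alone of these 6 stayed called, with 1.69 (1.13 to 2.51), and TRAV6D-3 was at 1.52 (0.821 to 2.80). TRAJ38 had a ratio of 2.09, which was 0.828 by copies, and TRAJ37 one of 0.341. J-alpha segments near the V segments were higher, with 1.16 (1.048 to 1.29), and far ones lower, with 0.740 (0.663 to 0.827). A Cys near the apex was at 0.934% in Treg and 0.275% in non-Treg cells, a ratio of 3.39 (1.75 to 6.59), but at 0.00708% and 0.187% of copies. TRAV15 to TRAV21 had a ratio of 0.603 (0.412 to 0.883), but 1.14 by copies. Short alpha CDR3s, with 1.04 (0.930 to 1.17), and long ones, with 0.821 (0.608 to 1.11), were not called in KO. At equal copies the Treg libraries held 0.0183 times the alpha clonotypes of non-Treg cells in KO and 0.0109 times in CTRL. Of the Treg alpha clonotypes, 22.7% in KO and 23.7% in CTRL were listed in the non-Treg library of the same genotype, and 28.0% and 21.2% in that of the other genotype. With the CTRL non-Treg list thinned to the 79955 clonotypes of the KO list, KO Treg clonotypes were at 22.7% in KO and 20.2% in CTRL non-Treg, and CTRL Treg clonotypes at 17.1% in CTRL and 21.2% in KO non-Treg. These shares depend on copies. Among Treg alpha clonotypes of at least 100 copies, against full lists, 45.6% in KO and 54.9% in CTRL were listed in the same genotype. In the other genotype 54.0% and 47.4% were. With the CTRL list thinned as above, KO Treg clonotypes of at least 100 copies were at 45.6% in KO and 38.5% in CTRL non-Treg. The CTRL ones were at 39.8% in CTRL and 47.4% in KO non-Treg. The order of same and other genotype thus turned for both, and the full-list order depends on list size. Numbers of sorted cells were not given in the labels, so a difference in clonotype number cannot be separated from one in cell input.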

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

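The results below have opposite directions in the 2 cell types: the KO over CTRL ratio lay above 1 in one of Treg and non-Treg cells and below 1 in the other, each with a counting interval that excludes 1. With 1 library per group the difference between the cell types was not tested. Each pair of ratios gives Treg cells first and non-Treg cells next.

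Among V-alpha segments, the ratios were 3.03 and 0.778 for TRAV13D-2, 0.0841 and 1.28 for TRAV17, 2.52 and 0.879 for TRAV3D-3, 0.132 and 1.12 for TRAV4D-3, and 3.10 and 0.897 for TRAV6D-3. Among J-alpha segments, they were 0.589 and 1.07 for TRAJ12, 2.38 and 0.938 for TRAJ32, 5.81 and 0.851 for TRAJ45, and 0.552 and 1.08 for TRAJ9. For the list of J-alpha segments near the V segments they were 1.43 and 0.903, and for the list far from them 0.754 and 1.07. Long alpha CDR3s had ratios of 2.59 and 0.888, but by copies were at 3.31% in KO and 3.23% in CTRL Treg cells. With TRAV copies collapsed, TRAV13D-2 had a Treg ratio of 0.533 (0.332 to 0.856), no longer opposite to that in non-Treg cells. Some Treg ratios came from few clonotypes: 1 in KO and 9 in CTRL for TRAV17, 16 and 4 for TRAV13D-2, and 23 and 3 for TRAJ45.

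For the beta chain, the ratios were 0.607 and 1.20 for TRBV13-3, 0.217 and 1.13 for TRBV26, 0.382 and 1.17 for TRBV29, 6.60 and 0.686 for TRBJ2-2, and 1.36 and 0.856 for TRBJ2-3. The Treg ratio of TRBJ2-2 came from 71 KO and 2 CTRL clonotypes. A Cys near the apex of the beta CDR3 had ratios of 0.149 and 1.51, but the non-Treg ratio was 0.840 (0.559 to 1.26) with error variants merged and 0.976 by copies, and the Treg ratio 0.597 (0.273 to 1.30) with low-copy shared clonotypes left out. By copies TRBV26 had ratios of 0.286 and 0.970, no longer opposite.

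Of these 18 results, 17 had a Treg ratio among clonotypes of at least 100 copies, an alternative added after seeing the data. Of those, 16 kept the direction, and TRAV4D-3 alone kept an interval that excludes 1, with 0.208 (0.0582 to 0.746). Among the 16 is TRAJ9, at 0.992 (0.385 to 2.56). These clonotypes are part of the list in which the directions were found, so agreement is partly built in. The exception in direction was TRBJ2-3, with 0.675 (0.263 to 1.73). Fewer clonotypes also widened the intervals: TRAV6D-3, for example, was at 3.47 (0.770 to 15.7). With low-copy shared clonotypes left out, 17 of 18 kept the direction and 14 an interval that excludes 1, and with merging as well 16 of 17 and 2.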

How the results depend on the processing

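The alternatives on Treg clonotypes of at least 100 copies, on low-copy clonotypes shared with non-Treg cells, on that step with merging, and on TRAV copies were chosen after seeing the data; the others were planned. No paired analysis was possible because each group holds 1 sample and the labels give no replicate numbers. Not run were clonotypes by nucleotides, which the files lack; a minimum of 2 copies and all rows instead of productive ones changed nothing, since no row fell under them. Counting copies gives no interval. Of 28 segments named for KO against CTRL in non-Treg cells, 28 stayed called with error variants merged and 23 at 5 copies, and 27 kept their direction at 5 copies and by copies. Of those named for KO against CTRL in Treg cells, 12 of 26 stayed called in the same direction with merging, 2 of 25 at 100 copies, 20 of 26 with low-copy shared clonotypes left out and 4 of 26 with both steps. Called or not, 26 of 26, 23 of 25, 25 of 26 and 22 of 26 kept their direction, in the same order. All these settings start from the lists in which the segments were picked, so agreement in direction is partly built in. Where a cause is not given below, the cause was not tested.

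Ratios are KO over CTRL unless Treg over non-Treg is said. By copies, TRBV31 in Treg cells turned to 0.677, TRBV13-2 to 0.999 and, in non-Treg cells, TRBV26 to 0.970. Treg over non-Treg ratios turned in KO to 0.828 for TRAJ38, 0.418 for TRBV31, 0.413 for TRBJ2-3, 1.14 for TRAV15 to TRAV21 and 2.04 for the superantigen-sensitive group. For an alpha Cys near the apex they turned to 0.0681 in CTRL and 0.0379 in KO. The TRBJ1 ratio was 1.04 in Treg and 1.27 in non-Treg cells, the beta Cys ratio 0.0129 and 0.976, and the hydrophobic doublet in Treg cells 689.8, from 2 CTRL clonotypes.

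With at least 5 copies, Treg clonotypes in CTRL and KO numbered 388 and 522 for alpha and 328 and 554 for beta. Thinned clonotype ratios were 1.69 for beta Treg and, Treg over non-Treg, 0.00634 and 0.00626 in CTRL and 0.0108 and 0.0153 in KO (alpha, beta). Called V segments were 8 for beta Treg and, Treg over non-Treg, 12 for CTRL alpha, 9 for KO alpha and 10 for KO beta. TRBV4 in non-Treg cells turned to 1.06, and in KO, Treg over non-Treg, TRBJ2-3 to 0.9499 and the superantigen-sensitive group to 1.34. The Cys ratio in non-Treg cells was 0.869 for alpha and 1.13 (0.717 to 1.79) for beta. Sharing with non-Treg of the same genotype was 28.4% and 28.9% for CTRL and KO alpha and 25.6% for KO beta.

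With error variants merged, Treg clonotypes were 256 and 390 for alpha and 101 for CTRL beta. Thinned ratios were 23.7 for beta Treg and, Treg over non-Treg, 0.00399 and 0.00187 in CTRL and 0.00779 for KO alpha. Called V segments were 6 for alpha Treg and, Treg over non-Treg, 5 and 3 in CTRL and 5 for KO alpha. The near J-alpha ratio in Treg cells was 1.16 (0.871 to 1.55), and the beta Cys ratio in non-Treg cells turned to 0.840. Sharing was 42.6% and 37.2% for CTRL and KO alpha and 14.9% and 94.7% for beta.

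With Treg clonotypes of at least 100 copies, 175 and 252 remained for alpha and 85 and 126 for beta. Thinned ratios were 1.48 for beta and, Treg over non-Treg, 0.00263 and 0.00153 in CTRL and 0.00487 and 0.00330 in KO. Called V segments were 2 for alpha and 0 for beta, and, Treg over non-Treg, 4 and 1 in CTRL and 5 and 4 in KO; fewer clonotypes also widen the intervals. TRBV31 turned to 0.385 and TRBJ2-1 to 1.01. Treg over non-Treg, TRBV31 turned to 0.233, TRBJ2-3 to 0.694 and the superantigen-sensitive group to 1.41 in KO, and the TRBV13 family to 0.986 in CTRL. The near J-alpha ratio was 1.46 and the TRBJ1 ratio 1.12. Sharing was 54.9% and 45.6% for alpha and 18.8% and 11.9% for beta, against full non-Treg lists, of which the CTRL ones are larger.

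With low-copy shared Treg clonotypes left out, KO beta kept 719 clonotypes, and thinned ratios were 1.31 and, Treg over non-Treg, 0.0186. Called V segments for KO beta, Treg over non-Treg, were 9. TRBV31 turned to 0.559 and, Treg over non-Treg in KO, to 0.399, TRBJ2-3 to 0.714 and the superantigen-sensitive group to 1.62. In Treg cells the TRBJ1 ratio was 1.08 (0.928 to 1.26) and the beta Cys ratio 0.597. The hydrophobic doublet was at 6.45 (1.498 to 27.8), from at most 2 CTRL clonotypes. Sharing, lowered by construction, was 16.99% and 15.2% for alpha and 3.30% and 2.23% for beta.

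With both steps, Treg clonotypes were 247 and 369 for alpha and 100 and 146 for beta. Thinned ratios were 1.46 for beta and, Treg over non-Treg, 0.00385 and 0.00185 in CTRL and 0.00737 and 0.00402 in KO. Called V segments were 6 and 0, and, Treg over non-Treg, 5 and 3 in CTRL and 4 and 1 in KO. TRBV31 turned to 0.587, TRBV13-2 to 0.978, TRBJ1-2 to 0.856 and TRBJ2-4 to 1.03. Treg over non-Treg in KO, TRBV31 turned to 0.599, TRBV26 to 1.049, TRBJ2-3 to 0.776 and the superantigen-sensitive group to 1.37. The near J-alpha ratio was 1.20 (0.893 to 1.61) and the TRBJ1 ratio 1.09 (0.760 to 1.57). Sharing was 41.3% and 33.6% for alpha and 15% and 10.96% for beta.

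With TRAV copies collapsed, TRAV13D-2 turned to 0.533 in Treg cells and, Treg over non-Treg in CTRL, to 1.17, since the name then covers more segments. Thinned to 0.1 of the copies of the smallest library, ratios were 2.67 for beta Treg and, Treg over non-Treg, 0.0228 and 0.0165 in CTRL and 0.0305 for KO alpha. By CDR3 alone, sharing was 44.4% and 42.7% for alpha and 16.6% for CTRL beta. With other windows, the beta Cys ratio in non-Treg cells was 1.055 (0.997 to 1.12), the hydrophobic doublet 0.913 (0.823 to 1.01), and the near J-alpha ratio in Treg cells 1.27 (0.983 to 1.64). The Treg comparisons are limited by few clonotypes, since 85 to 252 hold nearly all copies of each library, and in KO beta also by low-copy clonotypes shared with non-Treg cells.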

Other observations

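V-alpha and J-alpha segments were not paired at random in non-Treg cells of either genotype. TRAV17, TRAV19 and TRAV21/DV12, which lie at the J end of the V segments, were carried by 6.87% (6.58 to 7.16) of CTRL clonotypes with a J segment near the V segments and by 0.278% (0.226 to 0.339) of those with a far J segment, a 24.7-fold difference (20.2 to 30.3). In KO the shares were 7.09% (6.73 to 7.46) and 0.290% (0.229 to 0.362), a 24.4-fold difference (19.5 to 30.7). In Treg cells the near shares were 7.04% in CTRL, from 10 of 142 clonotypes, and 5.95% in KO, from 16 of 269, and no such clonotype had a far J segment among 241 and 240. These segments were singled out after their values were seen.

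Alpha clonotypes with many copies were listed in both genotypes. All 28 CTRL non-Treg alpha clonotypes of at least 1000 copies were also listed in KO, and 74.1% of those from 100 to under 1000 copies, against 14.1% of those of 2 copies. For the beta chain, 17 of 23 CTRL clonotypes of at least 1000 copies and 12.9% of those from 100 to under 1000 copies were shared. Of the KO non-Treg clonotypes of at least 1000 copies, all 36 alpha and 31 of 68 beta ones were listed in CTRL. From 100 to under 1000 copies, 64.5% of KO alpha and 15.3% of KO beta clonotypes were. Among Treg clonotypes of at least 100 copies, segments chosen after their values were seen were higher than in non-Treg cells in both genotypes. TRBJ2-4 was at 20% of CTRL Treg and 10.1% of CTRL non-Treg clonotypes, a ratio of 1.97 (1.29 to 3.02), and at 15.9% and 8.08% in KO, a ratio of 1.96 (1.31 to 2.94). Over all listed clonotypes, it was at 17.9% in CTRL Treg and 8.53% in KO Treg cells, and was not called in KO. TRAJ31 was at 9.14% and 5.49% in CTRL, a ratio of 1.67 (1.04 to 2.66), and at 9.92% and 5.53% in KO, a ratio of 1.79 (1.24 to 2.61).

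Of the tests that follow, those on public CDR3s, on T cell clones common to both cell types, on carried-over cells and on weaker removal of Cys-bearing receptors were chosen after their result was seen, and the patterns themselves were found in the same data. The test on common T cell clones was first run on alpha clonotypes of 2 copies, where the ratio of 0.967 (0.598 to 1.56) left it undecided against the bound set for it, and was then rerun on those under 20 copies, and later at equal list size.

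The first pattern was that low-copy beta clonotypes of the KO Treg library were mostly listed in the KO non-Treg library: 2319 of 2843 clonotypes under 20 copies, with 1.61% of the library's copies. Against public CDR3s made in many mice, the share at 2 copies listed in CTRL non-Treg was 0.136 (0.119 to 0.155) times that listed in KO non-Treg, and against carried-over cells, or RNA that holds both chains, KO non-Treg alpha clonotypes of at least 500 copies were listed in KO Treg 0.0922 (0.0522 to 0.149) times as often as the rate fitted on beta predicts, at 6.38% instead of 69.2%. Against common T cell clones as the whole cause, alpha clonotypes under 20 copies were listed in KO non-Treg 0.780 (0.600 to 1.01) times as often as in the larger CTRL list and 1.08 (0.813 to 1.44) times at equal list size, or 1.35 (0.793 to 2.29) at 2 copies, so a small excess is not excluded. Carry-over of KO non-Treg beta reads is a candidate explanation: a rate of 1 KO Treg copy per 286.7 KO non-Treg copies, fitted on clonotypes from 100 to under 500 copies, predicted that 66.0% of those of at least 500 copies appear, and 62.9% did, a ratio of 0.953 (0.907 to 0.997). That single rate is not a full account. It gave 0.0122% under 10 copies where 0.0729% were seen, and 0.425% against 0.575% from 10 to under 50. It gave 2.69% against 3.22% from 50 to under 100, and 92.8% against 85.3% (74.6 to 92.7) from 1000 copies. Whether beta reads crossed, and at which step, stays open.

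The second pattern was the higher TRBJ1 share of KO non-Treg cells, which held in each of 22 TRBV segments, with ratios from 1.19 to 1.79. Against PCR error variants and low-copy clonotypes, the ratio was 1.28 (1.26 to 1.30) among clonotypes of at least 20 copies. Against the V segment make-up, it was 1.29 (1.28 to 1.31) with KO weighted to the CTRL V shares, and against depth per clonotype 1.30 (1.28 to 1.31) with KO thinned to the CTRL copies per clonotype. An effect of the genotype on J choice or on later selection remains a hypothesis, since differences between single mice, between primer batches or between sorts were not tested and could give the same value. Among Treg clonotypes of at least 100 copies, the TRBJ1 share was 31.8% (22.1 to 42.8) in CTRL and 35.7% (27.4 to 44.7) in KO.

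The third pattern was the higher share of beta CDR3s with a Cys near the apex in KO non-Treg cells. Against the V and J make-up as its cause, the ratio was 1.48 (1.15 to 1.90) after weighting. Against a general shift of apex residues of that size, 0 of the other 19 residues had a ratio as far from 1, and 1, Trp, reached the lower end of the Cys interval, although 16 had smaller shifts with intervals that exclude 1, from 0.822 to 1.13. Errors that create a Cys remain a candidate explanation: the ratio was 0.984 (0.510 to 1.90), from 16 KO and 20 CTRL clonotypes, among those of at least 20 copies after merging, and 104 of 136 KO and 91 of 134 CTRL clonotypes with such a Cys had 2 to 4 copies. Weaker removal of Cys-bearing receptors in KO cannot be told apart from no change by the alpha chain, with 1.07 (0.901 to 1.28).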
